A study of Phaseolus coccineus with 4 samples.

How the data were processed

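Embryo proper and suspensor were each represented by 2 samples of scarlet runner bean, which the labels call biological replicates without saying which plants they came from, so p-values measure only the spread between these samples. Per the labels' protocols, plants of the cultivar Hammond's Dwarf Red Flower were grown with 16 h of light and 8 h of dark at 22 °C, seeds were fixed 6 days after hand pollination in 3 parts ethanol to 1 part acetic acid, and regions were cut by laser from paraffin sections of 6 µm. Input RNA was about 60 and 75 ng for embryo proper replicates 1 and 2 and 106 and 137 ng for suspensor replicates 1 and 2, so input differed by region. The RNA was amplified before labelling, from about 200 ng of cDNA, and hybridised to Affymetrix soybean arrays. Amplification from small inputs favours the 3' end of transcripts, and a bean transcript that differs from the soybean probe gives a weak signal, so a low signal does not show a low transcript level.

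The deposited values are intensities on a linear scale, 1 per probe set, made with GCOS 1.3 per the submitters' processing notes. The summary algorithm within GCOS and detection calls are not given in the sources used here. The mean intensity after leaving out 2% of probe sets at each end was 500 on each of the 4 deposited arrays, as global scaling by the authors would give, and the values were used on that scale.

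The array holds 61170 probe sets, of which 37593 are for soybean, 15820 for Phytophthora and 7530 for nematode. The background level of an array was the 95th percentile of its Phytophthora and nematode probe sets, 881 and 873 on the embryo proper arrays and 925 and 1034 on the suspensor arrays. Soybean probe sets above that level on at least 2 of the 4 arrays, 8972 in all, were tested. Values were taken as log2(intensity + 16), and suspensor was compared with embryo proper in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a variance trend and Benjamini-Hochberg adjustment over the tested probe sets. A fold is on the log2(intensity + 16) scale and understates changes of dim probe sets. Where both arrays of the dim region were below background, the fold is given as a bound: the mean log2 value of the bright region over, per dim array, the higher of the probe set's own value and the lowest soybean signal above background on that array. The bounds of the actin ratio use that same lowest signal for the 5' probe set.

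Gene symbols came from the platform annotation. Among soybean probe sets, 8677 had 1 symbol, of which 7001 were LOC placeholders, 370 had several symbols, from which no gene was named, and 28546 were unnamed here. The reference gene table, of 34063 bean genes, shared 0 gene identifiers with the annotation, so symbols were not updated and no positions are given. Among tested probe sets, 428 had a gene symbol other than a placeholder.

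The comparison, the background level, the lists and the genes to name were fixed before the data were examined. Named were the 12 genes per direction with the greatest log2 difference among those with a symbol, an adjusted p under 0.05 and no overlap of regions, 1 probe set per gene; up to 4 members of each list by smallest p; and the gibberellin biosynthesis list. Exactly 12 genes passed in each direction. The decision that a LOC placeholder is not a gene name, and the naming of 2 placeholders per direction, came after the data were in hand. Of 30 fixed lists, 17 matched no symbol in the annotation, which gives symbols and no descriptions, 4 matched symbols with no probe set that passed the background filter, and 3 had at least 5 measured members. Markers fixed for seed coat, endosperm and vascular tissue matched no symbol, so RNA from those tissues was not tested by them. A set of 33 further lists, by symbol, was written after the annotation had been read and before any difference between regions was computed. Lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the brightest, and with an estimated correlation and fry beside it.

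The fit was tested on simulated data with the real probe sets' means and the fitted spread, in which 200 of 8972 probe sets were changed. It recovered 0% of those changed 2-fold, 2% at 4-fold, 32% at 8-fold and 56% at 16-fold, with 3 false calls among 48. Most differences of 8-fold or less were thus missed in that simulation. The adjustment is less strict where more probe sets differ, and the data gave 247 calls, so recovery there may differ. With no probe set changed it made 0 calls. The simulated values were normal with the same spread in both regions. In the data the SD of the log2 difference between replicates was 1.07 in suspensor and 0.788 in embryo proper. The false calls of the simulation therefore need not hold for the data. Alternatives covered the pseudocount (1 and 64), quantile normalization, centring on the tested or on the Phytophthora and nematode probe sets, the background level and filter, probe sets with shared probes, the variance trend, a replicate block, and leaving out each array.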

Results

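Transcript levels were measured in both regions of the globular-stage embryo of the scarlet runner bean, Phaseolus coccineus, 6 days after pollination. The embryo proper gives rise to the plant, and the suspensor is the stalk that joins it to the surrounding seed tissue. Each region was represented by 2 samples cut from tissue sections with a laser, and each sample was hybridised to a soybean array, so the signals are those of bean RNA on probes made for another legume. Of 37593 soybean probe sets, 8742 and 8634 were above the background level on embryo proper arrays 1 and 2, against 8180 and 7328 on suspensor arrays 1 and 2. The number of arrays, 2 per region, limits the precision. The arrays also differed by region in their control probe sets. The median signal of the hybridisation spikes was 47294 and 60209 on the embryo proper arrays and 102229 and 161496 on the suspensor arrays. The 3' actin probe set had signals of 13961 and 5246 in embryo proper and 2766 and 4375 in suspensor. The 5' actin probe set was above background on suspensor array 2 alone, so the 3' to 5' ratio there, 3.59, stands beside lower bounds: at least 15.8 and 6.01 on the embryo proper arrays and at least 2.99 on suspensor array 1.

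The comparison of suspensor with embryo proper asks which transcripts differ in level between these regions at this stage. Among genes with a symbol, transcripts higher in the suspensor included GASA14, a member of a gibberellin-regulated peptide family, SS, a sucrose synthase, and ADH2, an alcohol dehydrogenase. GASA14 had a mean signal of 77700 ± 13900 (SD, n = 2) in suspensor and 11100 ± 540 (SD, n = 2) in embryo proper, a 6.97-fold difference with an adjusted p of 0.014. SS stood at 68700 ± 4920 (SD, n = 2) in suspensor against 11600 ± 2030 (SD, n = 2) in embryo proper, 5.98-fold higher (adjusted p = 0.014). ADH2 stood at 31700 ± 4160 (SD, n = 2) against 3750 ± 1780 (SD, n = 2), 8.91-fold higher (adjusted p = 0.016). FAD3C, an omega-3 fatty acid desaturase, was 4.83-fold higher in suspensor, with array signals of 95394 and 52950 against 14368 and 15036 (adjusted p = 0.028).

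The other genes with a symbol that were higher in suspensor were MET2, BZIP90, OAS-TL7, OSBP, ALDH5F2, MIPS4, GF14A and DXR1. MET2 was 12.1-fold higher by 1 of its 3 tested probe sets, with suspensor signals of 30464 and 10246. The brightest MET2 probe set was 1.87-fold higher and the dimmest at least 1.32-fold higher. BZIP90, a transcription factor of the bZIP class, was 11.1-fold higher, and its suspensor arrays differed widely, at 7641 and 26970. OAS-TL7, an enzyme of cysteine synthesis, was 6.76-fold higher. OSBP, an oxysterol-binding protein, was 5.69-fold higher, and ALDH5F2, an aldehyde dehydrogenase, was 4.85-fold higher. MIPS4, a myo-inositol-phosphate synthase, was 4.37-fold higher, with 1 of its 2 embryo proper signals below background. GF14A, a 14-3-3 protein, was 3.4-fold higher. DXR1, the reductoisomerase of the plastid isoprenoid pathway, was below background on both embryo proper arrays and was at least 2.74-fold higher in suspensor (adjusted p = 0.049), a call lost in 10 of 15 alternative settings. The further probe sets tested for GASA14, SS, MET2, BZIP90, GF14A and DXR1 did not pass the test. The called probe sets of GASA14, MIPS4 and GF14A have shared probes, so they may read more than 1 transcript.

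Transcripts higher in the embryo proper included PSAD, a subunit of photosystem I, COL10, a CONSTANS-like protein, IQD18 and PHYA, the photoreceptor phytochrome A. PSAD had signals of 11947 and 17685 in embryo proper and 733 and 734 in suspensor, below background on both suspensor arrays, so it was at least 14.6-fold higher in embryo proper (adjusted p = 0.0088). A further PSAD probe set stood at 0.37 on the log2 scale, below background on 1 array of each region, and did not pass (adjusted p = 0.72). IQD18 was at least 10.5-fold higher in embryo proper (adjusted p = 0.014). COL10 had signals of 4378 and 4854 against 73 and 44, at least 4.65-fold higher (adjusted p = 0.02). PHYA stood at 14800 ± 1350 (SD, n = 2) in embryo proper against 3380 ± 6.01 (SD, n = 2) in suspensor, 4.35-fold higher (adjusted p = 0.02).

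Further genes with a symbol that were higher in embryo proper were CAB3, VLXB, PIP2-6, SGF14f, AFB3B, GF14C, CCT-D and the gene listed as G. CAB3, a chlorophyll a/b-binding protein, was 5.42-fold higher by 1 of its 3 tested probe sets, while the brightest CAB3 probe set had a log2 difference of -0.5 that did not pass (adjusted p = 0.39). VLXB, a lipoxygenase, was 5.36-fold higher, and PIP2-6, a plasma membrane aquaporin, was 4.2-fold higher, and each was below background on 1 of the 2 suspensor arrays, as was CAB3. AFB3B, an auxin receptor F-box protein, was 3.72-fold higher, with signals of 14591 and 20660 against 5280 and 4101. The 14-3-3 proteins SGF14f and GF14C were 3.8-fold and 3.48-fold higher, the opposite direction to GF14A. The called probe sets of SGF14f, GF14C, GF14A, PIP2-6 and CAB3 have shared probes, so they may read more than 1 transcript. Without probe sets with shared probes, 17 of the 24 genes with a symbol were tested and 15 of these stayed called. CCT-D was 3.21-fold higher, and the gene listed as G was at least 5.07-fold higher.

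**Figure D1:**
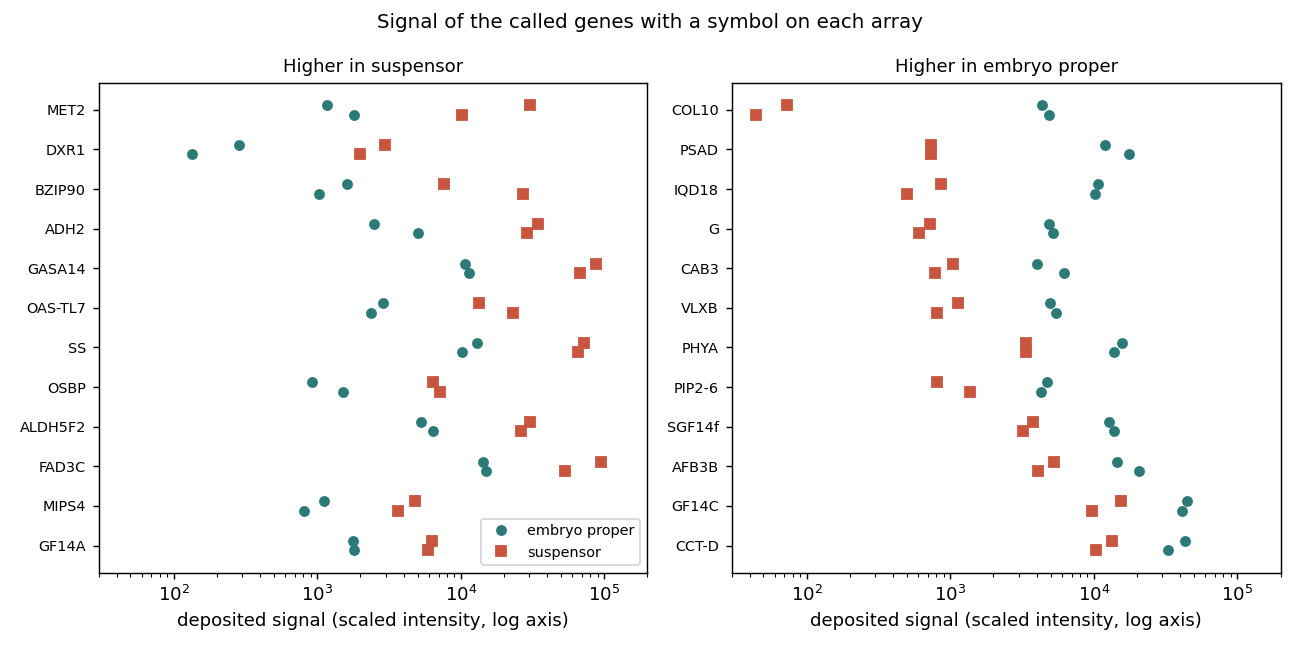
Deposited signal of the genes with a symbol that passed the test, on a log axis, with circles for the 2 embryo proper arrays and squares for the 2 suspensor arrays. The 12 genes at left were higher on both suspensor arrays and the 12 at right on both embryo proper arrays, with PSAD at 733 and 734 in suspensor.

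Some larger differences were found in probe sets with a placeholder symbol, named here after their values were seen. LOC100499847 had signals of 112102 and 112146 in embryo proper and 35 and 638 in suspensor, at least 113-fold higher in embryo proper, and LOC100801533 was at least 37.1-fold higher there. LOC732611 was higher in suspensor, with signals of 15655 and 11748 against 886 and 499 in embryo proper, the latter below background, and LOC100305372 was at least 4.51-fold higher in suspensor.

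Over all 8972 probe sets tested with limma, 80 were higher in suspensor and 167 higher in embryo proper at an adjusted p under 0.05, and 1802 had an unadjusted p under 0.05. The regions did not overlap in any of the 247 called probe sets, nor in 53.2% of all tested probe sets, where chance gives 33.3%. The calls split into 186 and 231 after quantile normalization and into 48 and 154 when arrays were centred on the Phytophthora and nematode probe sets. Replicates agreed less in suspensor than in embryo proper, with a Pearson r of 0.81 against 0.888 over tested probe sets. The SD of the log2 difference between replicates was 1.07 in suspensor and 0.788 in embryo proper. When 1 array is left out, the spread comes from the other region alone. Calls fell to 14 and 6 without embryo proper replicate 1 or 2 and rose to 1207 and 459 without suspensor replicate 1 or 2; of the 24 genes with a symbol, PSAD alone passed without embryo proper replicate 1, 0 passed without replicate 2, and 4 passed without a variance trend.

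**Figure D2:**
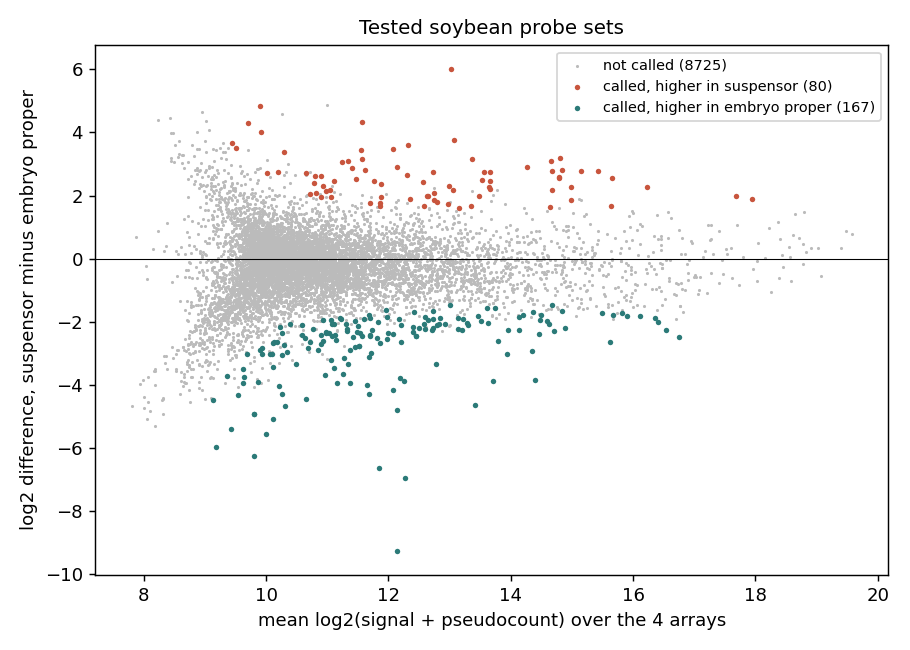
Log2 difference of suspensor minus embryo proper against the mean log2 signal over the 4 arrays for each of the 8972 tested probe sets. The 80 coloured points above 0 were called higher in suspensor and the 167 below 0 higher in embryo proper.

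Among the gene lists fixed in advance, 3 had at least 5 measured members. Of 6 genes for gibberellin inactivation and response, all members of the GASA family, GASA14 rose in suspensor and 5 did not pass. No inactivation gene was among them: GA2OX6 and GA2OX8 were below background on all 4 arrays. Of the members that did not pass, GASA32 had a log2 difference of 1.16 and GASA4 of -1.2, below background on 1 of the 2 suspensor arrays. GASA9 had signals of 2466 and 1086 in embryo proper and 1478 and 174 in suspensor, the last below background. Adjusted over the list alone, 2 were higher in suspensor, GASA14 and GASA32, and 1 in embryo proper. The probe sets of GASA14 and GASA32 share an identifier stem, so they may not be independent. A further GASA14 probe set stood at 0.64 and did not pass. Of 10 transporters, all plasma membrane aquaporins, PIP2-6 was lower in suspensor and 9 did not pass, with PIP2-4 at -0.82 and PIP1-7 at 0.95 on the log2 scale and PIP2-1, below background on both suspensor arrays, at least 1.62-fold higher in embryo proper; adjusted over the list alone the count was also 1. Of 48 transcription factors of other families 0 passed when each gene was represented by its brightest probe set, and 0 adjusted over the list alone. In that list BZIP90 had a log2 difference of 1.79. By the probe sets used, BZIP80, MYB185 and BZIP38 were below background on both embryo proper arrays. They were at least 6.78-fold, 1.73-fold and 2.2-fold higher in suspensor, without passing. A further BZIP80 probe set, below background on 1 array of each region, stood at 0.36 and did not pass (adjusted p = 0.75). These differences lie beside the regional difference in spike signal and the actin values given above.

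No fixed list shifted against the other genes in limma's camera test. The adjusted p was 0.25 for the gibberellin list, 0.71 for the aquaporins and 0.25 for the transcription factors, 0 had an unadjusted p under 0.05, and with an estimated correlation the adjusted p was 0.44, 0.74 and 0.44. By fry, which asks whether members move one way without comparing them with other genes, 1 of the 3 lists passed: the aquaporins, lower in suspensor (adjusted p = 0.0042). Of these 10 genes, 4 had a positive difference. Their mean log2 difference was -0.59, or -0.26 with PIP2-1 at its bound. The median log2 difference of the gibberellin list was 0.01, and it changed sign to -0.16 when arrays were centred on the Phytophthora and nematode probe sets; that of the transcription factors was -0.02, opposite in sign to its mean of 0.19 and its camera direction. GA20OX3, the gene matched by the gibberellin biosynthesis list, was below background on all 4 arrays, with signals of 38 and 305 in embryo proper and 772 and 527 in suspensor.

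Lists with fewer than 5 measured members were not tested, and their members with the smallest p were as follows. In the fatty acid list, FAD3C rose in suspensor, and FAD2-2 and FAD6.1 had log2 differences of 0.62 and 0.16 that did not pass; FAD6.1, below background on 1 array of each region, was -0.01 when centred on the Phytophthora and nematode probe sets. FAD2-3, below background on both embryo proper arrays, was at least 1.91-fold higher in suspensor and did not pass. In the heat shock list, HSP23.9, HSP90-1 and HSP90A1 had log2 differences of -0.81, -0.82 and 0.23, and HSP17.5-E had signals of 475, below background, and 1570 in embryo proper and 1507 and 1966 in suspensor. None of these passed. A further HSP90A1 probe set stood at -0.3. The sugar transporter SWEET28 had signals of 927 and 922 in embryo proper and was below background on both suspensor arrays, so no fold is given. SWEET17 stood at 0.22 and LEA-2 at 0.65, each below background on 1 array, and ERF3 at -0.14, which became 0.07 after quantile normalization. A further ERF3 probe set, below background on both embryo proper arrays, was at least 2.56-fold higher in suspensor and did not pass (adjusted p = 0.079).

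By detection alone, with no test, 906 soybean probe sets were above background on both embryo proper arrays and neither suspensor array, and 421 on both suspensor arrays and neither embryo proper array. With background at the 99th percentile these counts were 711 and 245. COL10, PSAD and IQD18 were among the former and DXR1 among the latter. A further 4480 probe sets were above background on all 4 arrays.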

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

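Both signals below lie in probe sets outside the comparison and were examined after the data were seen. The soybean ribosomal RNA probe sets whose identifiers lack RC were above background in their median on each array: 143799 and 217562 in embryo proper and 197351 and 186157 in suspensor. Of the Phytophthora and nematode probe sets, which served as background, 3 were over 10 times the background level on all 4 arrays, the brightest at 370079 and 477751 in embryo proper and 511698 and 832087 in suspensor. Of 1098 such probe sets above background on at least 2 arrays, limma called 0 in either direction.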

How the results depend on the processing

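Array weights were chosen after seeing the data, and the lists by symbol after the annotation was read but before differences were computed; the other settings were planned. The probe sets called higher in suspensor and in embryo proper, 80 and 167 as reported, became 134 and 293 with background at the 99th percentile, 192 and 334 with detection on all 4 arrays, 48 and 111 without shared probes and 21 and 66 without a variance trend. They were 186 and 231 after quantile normalization, 129 and 196 when centred on the tested median and 48 and 154 when centred on the Phytophthora and nematode probe sets. These centrings moved the median log2 difference from -0.18 to -0.062 and -0.35. Stricter filters test fewer probe sets; for the others the cause was not tested. With the replicate block the counts were 138 and 292. Same-numbered arrays did not deviate together (correlation -0.024 across probe sets). No label says what a shared number stands for, so pairing was not assumed, and this correlation cannot exclude it. Leaving out 1 array gave 3 to 153 and 3 to 1054, where the lone array was assumed to vary like the other region and the spread came from that region alone. In each of these settings all main calls that were tested kept their sign. Where 1 array was left out this was fixed in advance, since the regions did not overlap in any call. The replicate block leaves the difference itself unchanged. The centrings moved values by far less than the smallest called log2 difference, 1.46 in absolute size. The kept signs in those settings, also of the named genes, are therefore no evidence for the calls. Requiring a fold of at least 2 removed no call. Of the 24 named genes, 18 stayed called with Phytophthora and nematode centring, 4 without a variance trend, and 1 and 0 without embryo proper replicate 1 or 2; none changed sign. DXR1 was lost in 10 of 15 settings. Fixed lists higher in suspensor numbered 1 with no filter on dim probe sets, the fatty acid list (adjusted p = 0.0082). Lists by symbol, 1 as reported, numbered 0 with no filter, with detection on all 4 arrays, without shared probes or with an estimated correlation, 2 without a variance trend, and 0 to 1 when 1 array was left out; without embryo proper replicate 2 the 1 was phosphoenolpyruvate carboxylase (adjusted p = 0.0096), and fatty acid and lipid synthesis was lost. Detection in suspensor alone, 421, was 245 at the 99th percentile; rescaling arrays cannot move it, since the background level moves with the array. Signal over background limits the rest: 24694 soybean probe sets were above background on no array.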

Other observations

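The lists in this paragraph and the next were written by symbol after the annotation had been read, and their tests count as chosen afterwards; the tests of the patterns that follow were set before their results were seen. Of 16 with at least 5 measured members, camera called 1, fatty acid and lipid synthesis, with 7 of 8 members positive, a median log2 difference of 0.57 and an adjusted p of 0.017. The call was lost in camera with the estimated correlation, 0.45 (adjusted p = 0.63), and the list did not pass by fry (adjusted p = 0.26). FAD3C rose in suspensor and 7 members did not pass, among them DGD1, a galactolipid synthase, at 1.63, or -0.01 by its dimmer probe set, and FAD2-2 at 0.62 on the log2 scale. Phosphoenolpyruvate carboxylase genes had a median of 1.12 over 5 members, or 0.48 with the 2 members below background on both embryo proper arrays at their bounds, and did not pass (adjusted p = 0.099). PEPC7, one of these, was at least 2.31-fold higher in suspensor without passing. The probe sets of these 2 members, PEPC7 and PPC1, share an identifier stem, so they may not be independent. The carboxylase list passed in camera without a variance trend (adjusted p = 0.031). Which list passed also depended on the array left out. The call of fatty acid and lipid synthesis was lost without suspensor replicate 1 and without embryo proper replicate 2, and in the latter setting the carboxylase list passed. With the estimated correlation, 0.7, the camera adjusted p of the carboxylase list was 0.63.

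The 7 photosynthesis genes did not shift together (adjusted p = 0.95): PSAD was lower in suspensor, whereas ELIP and FTRC stood at 1.44 and 1.28 without passing. Their median was -0.06, opposite in sign to the camera direction, and 0.22 after quantile normalization. Of 7 measured 14-3-3 genes, GF14A was higher in suspensor and SGF14f was lower, both by probe sets with shared probes. The other 5 did not pass, counting GF14C by its brightest probe set (-0.98), and the camera adjusted p was 0.45 for the list. Among antioxidant enzymes (adjusted p = 0.15), DHAR3 stood at 1.84, and AOX3 had signals of 3124 and 4832 in embryo proper and 1310 and 254 in suspensor, the last below background; a dimmer AOX3 probe set stood at 0.45. The auxin receptor TIR1C had signals of 3670 and 3802 against 1058 and 115, the last below background, and did not pass. Flavonoid genes, which the seed coat also expresses, had a median of 0.25 over 13 members (adjusted p = 0.36). Of 11 sieve element probe sets and 25 of storage proteins and inhibitors, 0 were above background on at least 2 arrays. The gibberellin and aquaporin lists by symbol had the same measured members as the fixed lists, so they repeat those tests. The MYB and bZIP lists shared members with the fixed list of transcription factors. Adjusted p in the remaining lists was 0.35 for gibberellin and for cell wall genes, 0.26 for sugar use, nitrogen assimilation and bZIP, 0.36 for seed maturation, 0.44 for MYB, 0.72 for sulfur and methionine, 0.81 for aquaporins and 1 for WRKY.

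Calls in probe sets with 1 symbol split into 40 higher in suspensor and 45 higher in embryo proper, and those with several symbols into 3 and 5. Calls in probe sets without a symbol split into 37 and 117. Over all kinds, more probe sets were called higher in embryo proper, 67.6% of calls, an excess that lay mostly in probe sets without a symbol. Without suspensor replicate 2 the share was 68.4%, above the bound of 60% set beforehand for an excess that does not come from that array alone. The spread in that fit came from the embryo proper pair alone, so the share does not settle whether that array was the source. The median log2 difference over tested probe sets went from -0.18 to -0.013 without suspensor replicate 2, and to -0.29 without suspensor replicate 1. The share was 87.3% of 1207 calls without suspensor replicate 1, and 50% of 14 and of 6 calls without embryo proper replicate 1 or 2, so the excess was not seen in the few calls left when 1 of the embryo proper arrays was dropped. Dimmer suspensor arrays that shift all values stay open: the share was 55.4% after quantile normalization, between the bounds of 55% and 60% set beforehand, and 60.3% and 76.2% when arrays were centred on the tested or on the Phytophthora and nematode probe sets. Quantile normalization raised the embryo proper calls from 167 to 231 and the suspensor calls from 80 to 186. Its lower share thus came with more suspensor calls rather than with a smaller number of embryo proper calls. That does not decide whether a shift added to the excess. The regions also differ in input RNA, and a biological difference stays open and untested.

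ADH2 and SS are induced by low oxygen in many plants, so a low-oxygen response in suspensor might also raise alanine aminotransferase genes. Only ALAAT1 was measured, with a log2 difference of -0.51 (SE 0.46), while ALAAT2 and ALAAT3 were below background on all 4 arrays. Without embryo proper replicate 2 the ALAAT1 difference was 0.05, and it stayed negative when any other single array was left out. The test set beforehand was on the median of all 3 genes and took them to be measurable; with ALAAT1 alone that median is not known, so a shared response stays open. ALAAT1 itself did not pass in any setting.

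DXR1 acts upstream of gibberellin synthesis, and the hypothesis for its higher level in suspensor was that the change covers the other named isoprenoid and gibberellin synthesis genes DXR2, GPPS and GA20OX3. The test had nothing to measure: of these genes, 0 were above background on at least 2 arrays, so the hypothesis stays open.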
